A study of Rattus norvegicus with 10 samples.

How the data were processed

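RNA from rat nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc, was measured on 10 arrays. The cells came from male Sprague Dawley rats, and 5 arrays held cells transduced with a lentivirus that carries a control short hairpin RNA in the pLKO.1 vector (ShCtrl), and 5 held cells transduced with a hairpin against Bnip3 (ShBNIP3). Per the labels, RNA was collected 4 days after transduction. The protocol text for the RNA extraction also speaks of disc tissue from mice, which matches neither the organism nor the treatment of these samples, and it was not used for the design. The group of each array was taken from its title, and the title numbers (1 to 5 for ShCtrl, 6 to 10 for ShBNIP3) are used here as array numbers. No label says whether the arrays of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

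The deposited values are log2 expression values, 1 per probeset and array, which the authors obtained by sst-rma normalization of GeneChip WT Plus hybridisations, per the labels. The submitters' processing notes name the Transcriptome Analysis Console, with no version given in the sources used here. The labels also name a detection filter, a false discovery rate threshold written as 0.05% and a fold change of 2. No detection p-values were used here, and the value table was used as deposited, on its own scale. Array medians lay between 6.18 and 6.22, so the arrays were already on a common scale. For arrays, their number limits the precision.

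The table held 24834 probesets. The 1646 control probesets were left out of the tests, which leaves 23188. Of these, 15049 carry 1 gene symbol in the platform annotation, 0 carry several and 8139 carry none. All 15049 Entrez identifiers were found in the RefSeq gene table of assembly GRCr8, and 0 symbols changed. They name 15037 genes, of which 10 have more than 1 probeset. For a gene with several probesets the one with the highest mean over all arrays was used in the gene lists. Unnamed probesets were tested and counted but are not named. Of the probesets tested, 443 hold the same 10 values as at least 1 other probeset, and they stand for near-identical copies that the array cannot tell apart. The value of Ftl1, a ferritin light chain gene, is shared in this way by 2 probesets. Sox9 and the 13 transcripts of the mitochondrial genome have no named probeset and are not analysed here by name.

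Differences are ShBNIP3 minus ShCtrl on the log2 scale and were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 23188 probesets, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes are from this fit. A second count added a change of at least 2-fold, the threshold in the labels. The level of Bnip3 was also tested with an exact two-sided permutation test of the group means. A probeset was taken as at background in a group when it lay, on every array of that group, under the 95th percentile of the 23 antigenomic background probesets of that array. Where 1 group was at background, the fold is given as "at least N-fold", the brighter group's mean over the background level of the other group, and where both were, no fold is given. Folds near background understate the change.

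There were 38 gene lists, fixed before the data were examined, with 793 of their 914 entries measured: mitophagy receptors, core autophagy, lysosome, glycolysis, pyruvate oxidation and TCA cycle, respiratory complex I, respiratory complexes III, IV and ATP synthase, mitochondrially encoded transcripts, mitochondrial ribosome, mitochondrial dynamics and biogenesis, mitochondrial chaperones and proteases, HIF-1 targets outside glycolysis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, ATF4 targets, ER chaperones, NRF2 and antioxidant genes, cartilage-type matrix, matrix proteases, nucleus pulposus markers, inflammatory cytokines and NF-kB targets, interferon response, cell cycle, p53 targets and senescence, regulators of apoptosis, the YAP and Hippo pathway, MAPK feedback genes, TGF-beta and BMP targets, and markers of 9 other cell types or tissues (endothelium, macrophages and leukocytes, annulus fibrosus and fibroblasts, smooth muscle and pericytes, skeletal muscle, Schwann and neural cells, bone and hypertrophic cartilage, adipocytes, erythroid cells). The 37 lists with at least 5 measured genes were tested with camera (limma) at its preset correlation of 0.01, competitive and two-sided, with Benjamini-Hochberg adjustment over these lists. Each was also tested with camera at a correlation estimated from the data and with fry (limma), which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Member counts are given after adjustment over all probesets and adjusted over the list alone.

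The genes named in the text follow a rule fixed before the data were examined. Bnip3 comes first. Then come the 12 largest rises and 12 largest falls among named genes past the threshold whose 5 ShBNIP3 values all lie on 1 side of all 5 ShCtrl values. From each list come up to 4 members past the threshold with the largest changes, or the 1 or 2 largest where none passed. Bnip3l, Pink1, Hif1a, Slc2a1, Acan, Col2a1 and Sox9 were to be given in any case, and 1 other item of the rule is not reported here. Genes outside this rule are marked where they appear.

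Before use, the fit was tested on simulated data made from these 23188 probesets, with 67, 67 and 66 of them changed by 0.5, 1 and 2 on the log2 scale. Of these, 13.4%, 62.7% and 97% were recovered, and 6 of 121 calls were false. The simulated values were drawn independently for each probeset and array. Far fewer probesets were changed than passed in the real data, so these rates may not hold there. Camera on simulated data of 15037 genes found a list of 20 genes shifted by 0.5 in 20 of 20 simulations and called 0 of 740 unshifted lists, with gene values drawn independently.

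The alternatives tried were filters on dim probesets (above the 25th or 50th percentile of mean signal), quantile normalization or median centring on top of the deposited values, a trended and robust variance, array weights, a threshold of 0.01, complete separation of the groups, limma's treat with a fold of 1.2, each of the 10 arrays left out in turn, and for lists the estimated correlation, fry, the mean over probesets and no members shared between lists. After seeing the data, leaving out ShCtrl array 4 and ShBNIP3 array 10 together, and treating these arrays as a block, were added, because they stood apart from the rest of their groups. Array quality was read from 399 exon and 1153 intron control probesets. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.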

Results

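The study asked what happens to gene expression in nucleus pulposus cells of the rat disc when Bnip3, a receptor on the outer mitochondrial membrane that marks mitochondria for removal by autophagy (mitophagy), is knocked down. Whole-transcript arrays measured RNA of 5 samples with a control hairpin (ShCtrl) and 5 samples with a hairpin against Bnip3 (ShBNIP3), 4 days after transduction. Levels are log2 values as the authors normalized them, with means given ± SD. Pearson correlations between an array and the others of its group averaged 0.992 for 8 of the arrays, 0.983 for ShCtrl array 4 and 0.986 for ShBNIP3 array 10.

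Bnip3 was lower on every ShBNIP3 array than on any ShCtrl array. Its level was 14.6 ± 0.79 in ShCtrl and 11.4 ± 0.77 in ShBNIP3 (SD, n = 5 each), a log2 difference of -3.21 (SE 0.40) that left 10.8% of the control level, with a limma adjusted p of 0.00020. The exact two-sided permutation p was 0.0079, the smallest that 5 against 5 arrays can give. Its paralog Bnip3l (Nix), another mitophagy receptor, also fell, by 0.66 on the log2 scale (SE 0.12, limma adjusted p = 0.0023). Pink1, the kinase that starts the other main mitophagy route, differed by -0.12 (SE 0.14, limma adjusted p = 0.68), and Hif1a, the oxygen-regulated transcription factor that drives Bnip3, by -0.02 (SE 0.20, limma adjusted p = 0.97).

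**Figure D1:**
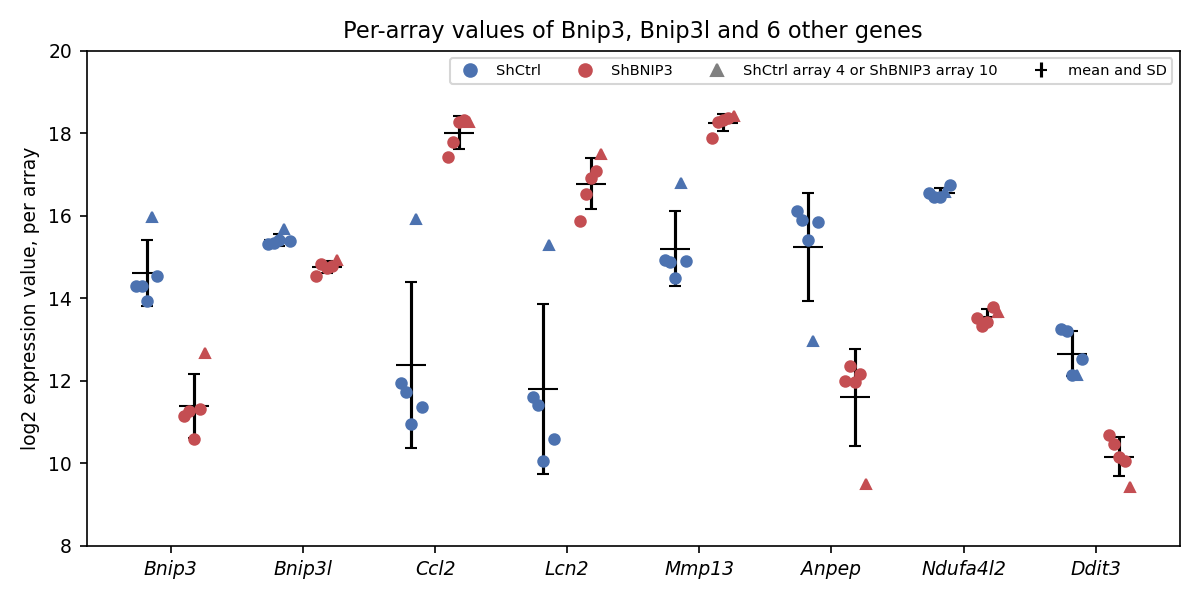
Log2 expression values (vertical axis) of 8 genes on each of the 5 ShCtrl and 5 ShBNIP3 arrays, with horizontal bars for the mean and error bars for the SD. Triangles mark ShCtrl array 4 and ShBNIP3 array 10. Bnip3 averaged 14.6 in ShCtrl and 11.4 in ShBNIP3, and Ccl2 averaged 12.4 and 18.0.

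Across the arrays 3590 of 23188 probesets changed (15.5%), of which 1765 rose and 1825 fell. Among named genes 2577 of 15037 changed, 1334 up and 1243 down. A change of at least 2-fold was found for 969 probesets, 333 higher and 636 lower, so 65.6% of these fell. Both groups were completely separated for 2989 probesets (12.9%), where chance gives 0.794%. Without ShCtrl array 4 and ShBNIP3 array 10, 4622 probesets changed and 1168 changed by at least 2-fold. Of the probesets called with all arrays, 3311 of 3590 and 890 of 969 were among these, all in the same direction.

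Several of the largest rises were in secreted inflammatory and acute-phase genes. The monocyte chemokines Ccl2 and Ccl7 rose 49.6-fold (log2 5.63, SE 0.73, limma adjusted p = 0.00025) and 44.6-fold (log2 5.48, SE 0.58, limma adjusted p = 5.61e-05). The iron-binding acute-phase protein Lcn2 rose 31.8-fold and complement component C3 24.8-fold. Without ShCtrl array 4, the log2 rises of Ccl2, Lcn2 and C3 were 6.52, 5.87 and 5.22. Further rises were in Mmd (20.5-fold), the secreted phospholipase Pla2g2a (16.9-fold), the acute-phase glycoprotein Orm1 (14.1-fold), the bone morphogenetic protein Bmp2 (10.2-fold), the amino acid transporter Slc43a2 (8.40-fold), the collagenase Mmp13 (8.33-fold) and the Wnt antagonist Sfrp4 (8.20-fold). Tnfrsf9, a costimulatory receptor at background in ShCtrl, rose at least 2.57-fold.

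The largest falls were in genes of other kinds. The aminopeptidase Anpep fell 12.6-fold (log2 -3.65, SE 0.63, limma adjusted p = 0.0018) and the adenylyl cyclase Adcy8 9.89-fold (log2 -3.31, SE 0.33, limma adjusted p = 3.12e-05). Lims2 fell 8.78-fold, and Mxi1, a MYC antagonist and HIF-1 target, 8.61-fold. Ndufa4l2, a hypoxia-induced inhibitor of mitochondrial respiration, fell 8.05-fold (log2 -3.01, SE 0.12, limma adjusted p = 4.36e-08). The ferritin light chain gene Ftl1, whose probeset shares its values with 1 unnamed probeset, fell 7.49-fold. The proto-oncogene Myc fell 7.28-fold, and Fam234a, Igfbp4, Hspb7, Sumf2 and Rhbdd2 between 6.50-fold and 7.50-fold. Without ShCtrl array 4 and ShBNIP3 array 10 the log2 fall of Igfbp4 was -3.47 in place of -2.83.

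**Figure D2:**
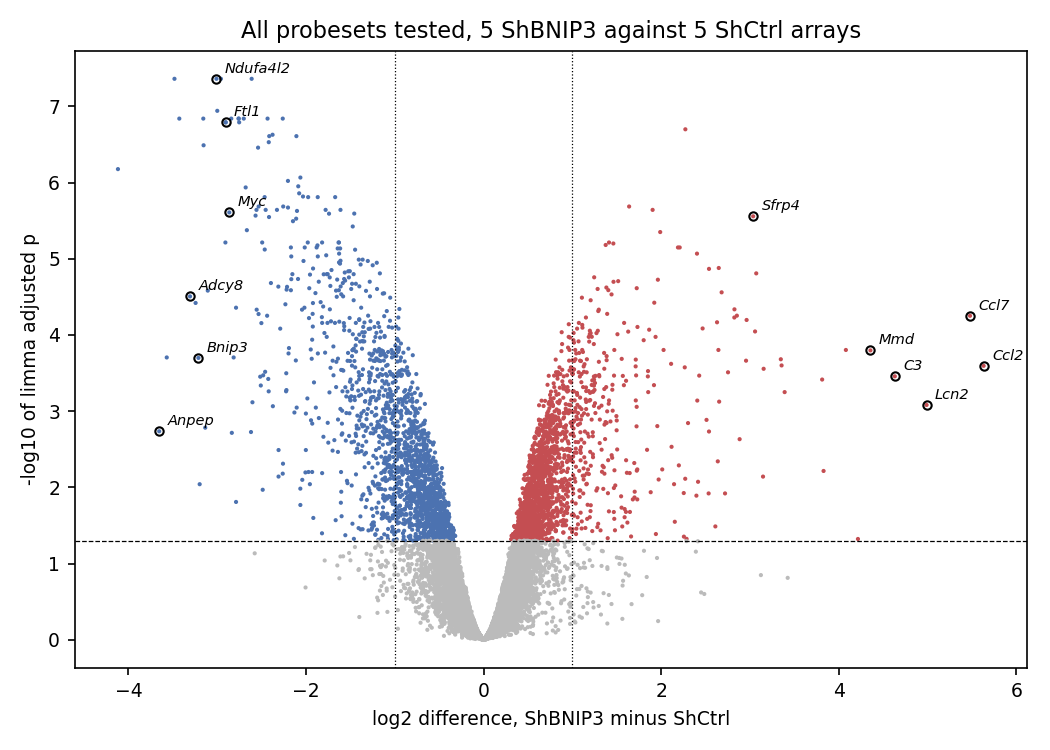
Log2 difference, ShBNIP3 minus ShCtrl (horizontal axis), against -log10 of the limma adjusted p (vertical axis), 1 point per probeset, with 5 arrays in each group. Points above the dashed line passed the threshold of 0.05, red for 1765 rises and blue for 1825 falls, and dotted lines mark 2-fold changes. Ccl2, Ccl7, Lcn2, C3 and Mmd lie farthest to the right among the circled genes.

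Inflammatory genes rose in part. Of 28 measured cytokines, chemokines and NF-kB targets, 12 rose and 0 fell (14 and 0 adjusted over the list alone, 17 and 0 at an unadjusted p under 0.05 in limma), with Ccl2, Ccl7, Lcn2 and C3 at the top and a median log2 difference of 1.48. The list shifted up in camera (adjusted p = 2.57e-06, and adjusted p = 0.717 with an estimated correlation). Without ShCtrl array 4 and ShBNIP3 array 10, 21 members rose and the median was 1.90. Array 4 itself held high values, with list members a median of 2.76 above the other 4 ShCtrl arrays, and on array 10 they lay 0.96 above the other 4 ShBNIP3 arrays. Matrix proteases and their inhibitors went both ways, 7 of 20 up and 3 down (9 and 5 adjusted over the list alone; camera adjusted p = 0.289). The rises included Mmp13, the stromelysin Mmp10 (6.29-fold), the gelatinase Mmp9 (6.25-fold) and the elastase Mmp12 (5.53-fold).

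Macrophage and leukocyte markers were not called as a list, and the share that passed was near the 17.1% of all named genes. Of 17 measured, 3 rose and 0 fell (3 and 0 adjusted over the list alone and at an unadjusted p under 0.05 in limma; camera adjusted p = 0.523). Cd68 rose 2.83-fold and Cd14, a co-receptor for bacterial lipopolysaccharide that other cells also make, 2.17-fold, while Cd53 rose within the background range. The median of the list was 0.08, and 14 members were at background on all 10 arrays. Interferon response genes had 3 of 27 up and 0 down (3 and 0 adjusted over the list alone, 3 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.603), with B2m, the light chain of MHC class I, 1.97-fold higher.

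Feedback genes of MAPK signalling, 7 of 23 up and 1 down, had the same counts adjusted over the list alone and a camera adjusted p of 0.0667 (adjusted p = 0.717 with an estimated correlation). The ERK phosphatase Dusp6 rose 5.29-fold, the early response gene Ier3 4.42-fold and Phlda1 3.30-fold, and Myc was the member that fell. The camera adjusted p of this list was 0.0152 without ShCtrl array 4, 0.0484 without ShCtrl array 2, 0.0267 without ShBNIP3 array 6, 0.0461 without ShBNIP3 array 7 and 0.0316 without arrays 4 and 10, the last with an adjusted p = 0.687 with an estimated correlation. TGF-beta and BMP targets had 4 of 22 up and 3 down, also when adjusted over the list alone (camera adjusted p = 0.919). Bmp2, the feedback inhibitor Pmepa1 (4.56-fold) and the receptor Tgfbr1 (2.28-fold) rose. The matrix protein Tgfbi fell 2.29-fold (limma adjusted p = 0.021, over 0.05 in 5 of 10 fits with 1 array left out, at most 0.0549).

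Targets of ATF4, the transcription factor of the integrated stress response, fell in part. Of 28 measured, 11 fell and 0 rose (15 and 2 adjusted over the list alone, and 15 and 2 at an unadjusted p under 0.05 in limma), and the list shifted down in camera (adjusted p = 0.00013, and adjusted p = 0.717 with an estimated correlation). Ddit3 (CHOP) fell 5.67-fold (log2 -2.50, SE 0.27, limma adjusted p = 6.99e-05) and the alanyl-tRNA synthetase Aars1 4.13-fold (log2 -2.04, SE 0.21, limma adjusted p = 4.66e-05). The pseudokinase Trib3 fell 6.90-fold (limma adjusted p = 0.016, or 0.056 with a trended and robust variance). On ShCtrl array 4 and ShBNIP3 array 10 the members lay a median of -0.62 and -0.49 from the other 4 arrays of their groups, and without these arrays 15 fell and 1 rose. ER chaperones had 3 of 20 up and 3 down (3 and 4 adjusted over the list alone; camera adjusted p = 0.694). The protein disulfide isomerase Pdia6 fell 2.85-fold, Herpud1 2.75-fold and Sel1l, a part of the ER degradation machinery, 2.19-fold, while Dnajc3 rose 1.78-fold. Of 25 NRF2 and antioxidant genes, 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.225, or 0.0472 without arrays 4 and 10, where the adjusted p = 0.609 with an estimated correlation), and Ftl1 had the largest fall. The peroxiredoxin Prdx3 rose 1.58-fold (limma adjusted p = 0.042, over 0.05 in 8 of 10 fits with 1 array left out, at most 0.106).

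Glycolysis genes fell in part. Of 23 measured, 6 fell and 0 rose, also when adjusted over the list alone and at an unadjusted p under 0.05 in limma. The platelet-type phosphofructokinase Pfkp fell 2.70-fold (log2 -1.44, SE 0.26, limma adjusted p = 0.0021), the hexokinase Hk1 2.44-fold, the aldolase Aldoc 2.30-fold and the enolase Eno2 2.00-fold. The glucose transporter Slc2a1 differed by -0.52 (SE 0.38, limma adjusted p = 0.44), and by -0.10 without ShCtrl array 4 and ShBNIP3 array 10. Without these arrays 7 members fell and 2 rose, the hexokinase Hk2 (log2 0.89, limma adjusted p = 0.00071) and the transporter Slc2a3 (log2 0.71, limma adjusted p = 0.0075), both named after their values were seen. As a whole the list shifted down in camera (adjusted p = 0.0017, and adjusted p = 0.717 with an estimated correlation). Without ShCtrl array 4, on which the members lay a median of 0.69 above the other ShCtrl arrays, the camera adjusted p was 0.0821 and the median log2 difference -0.13 in place of -0.23.

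HIF-1 targets outside glycolysis had 5 of 21 down and 0 up (6 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05 in limma), with Mxi1 and the stress-responsive Ndrg1 (5.59-fold) falling most. The camera adjusted p was 0.0017 (adjusted p = 0.717 with an estimated correlation), and 0.202 without ShCtrl array 4, with a median log2 difference of -0.27 in place of -0.31. On that array the members lay a median of 1.40 above the other ShCtrl arrays. On ShBNIP3 array 10 the medians of the glycolysis and HIF-1 lists lay 0.09 and 0.28 above the other ShBNIP3 arrays. Without both arrays 8 members fell and 1 rose, with a camera adjusted p of 0.0336 (adjusted p = 0.758 with an estimated correlation).

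Nuclear genes for mitochondrial proteins changed in different directions. Complex I subunits rose in part, 8 of 31 up and 0 down (13 and 0 adjusted over the list alone, 15 and 0 at an unadjusted p under 0.05 in limma), and shifted up in camera (adjusted p = 0.0017, and adjusted p = 0.717 with an estimated correlation). Ndufa1 rose 1.58-fold, Ndufb4 1.55-fold and Ndufa7 1.55-fold. The members lay a median of -0.36 and -0.12 from the rest of their groups on ShCtrl array 4 and ShBNIP3 array 10. Complexes III, IV and ATP synthase had 9 of 32 up and 6 down (13 and 6 adjusted over the list alone; camera adjusted p = 0.230). Here the largest changes were falls, in the cytochrome oxidase subunit Cox5b (2.88-fold) and in Atp5mc2 (2.74-fold) and Atp5mc1 (1.97-fold), which encode the same ring subunit of ATP synthase. The list of 13 mitochondrially encoded transcripts had 0 members with a named probeset. Pyruvate oxidation and TCA cycle genes had 4 of 23 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.603), among them the succinate dehydrogenase subunit Sdhc and the pyruvate dehydrogenase subunit Pdha1, 1.95-fold and 1.73-fold lower, and Dld, 0.59 higher on the log2 scale.

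Mitochondrial ribosomal proteins had 7 of 63 up and 4 down (7 and 5 adjusted over the list alone, camera adjusted p = 0.203). Mrpl51 and Mrpl37 were 2.32-fold and 2.19-fold lower, and Mrpl42 and Mrpl54 1.85-fold and 1.84-fold higher. On ShCtrl array 4 the members lay a median of -0.36 from the other ShCtrl arrays. Without ShCtrl array 4 and ShBNIP3 array 10, 8 members rose and 8 fell. Of 24 genes of mitochondrial dynamics and biogenesis, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.154). The fission GTPase Dnm1l rose 1.58-fold and the mitochondrial transcription factor Tfb2m 1.61-fold, while the fusion GTPase Mfn2 fell 1.27-fold (limma adjusted p = 0.0499, over 0.05 in 9 of 10 fits with 1 array left out, at most 0.117). Mitochondrial chaperones and proteases had 3 of 14 up and 2 down (4 and 2 adjusted over the list alone; camera adjusted p = 0.481). Atf5, a regulator of the mitochondrial unfolded protein response, fell 3.85-fold and the matrix protease Lonp1 2.26-fold, while the membrane protease subunit Spg7 rose 1.80-fold.

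Mitophagy receptors and adaptors other than Bnip3 had 2 of 18 up and 3 down (2 and 4 adjusted over the list alone; camera adjusted p = 0.594). The adaptor Sqstm1 (p62) fell 2.08-fold, the inner membrane receptor Phb2 1.98-fold and Bnip3l 1.58-fold, while Fundc2 rose 1.58-fold. Core autophagy genes had 5 of 29 up and 1 down, also adjusted over the list alone (camera adjusted p = 0.603). Gabarapl2, a member of the ATG8 family, rose 1.77-fold and the kinase Ulk2 rose by 0.58 on the log2 scale, and Wdr45 fell 1.87-fold. Of 33 lysosomal genes 11 rose and 5 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.154). The acid lipase Lipa fell 4.22-fold and the cathepsin Ctsl 1.91-fold, while the sialidase Neu1 rose 1.91-fold.

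Cholesterol synthesis genes rose in part. Of 20 measured, 9 rose and 0 fell (10 and 0 adjusted over the list alone and at an unadjusted p under 0.05 in limma), and the list shifted up in camera (adjusted p = 0.0017, and adjusted p = 0.717 with an estimated correlation). Hsd17b7 rose 3.78-fold (log2 1.92, SE 0.27, limma adjusted p = 0.00046), the isopentenyl diphosphate isomerase Idi1 2.23-fold and the methylsterol oxidase Msmo1 2.08-fold. The members lay a median of -0.61 from the other ShCtrl arrays on ShCtrl array 4 and -0.14 from the other ShBNIP3 arrays on ShBNIP3 array 10. Fatty acid synthesis and storage genes had 2 of 21 up and 5 down (4 and 5 adjusted over the list alone; camera adjusted p = 0.603). Their transcription factor Srebf1 fell 4.00-fold, the acyltransferase Agpat2 2.47-fold and ATP citrate lyase, Acly, 2.02-fold. Fatty acid oxidation genes had 3 of 20 up and 2 down, also adjusted over the list alone (camera adjusted p = 0.670). Cpt1a, which controls entry of fatty acids into mitochondria, rose 3.31-fold, and Hadh and Acadl fell 2.21-fold and 2.04-fold.

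**Figure D3:**
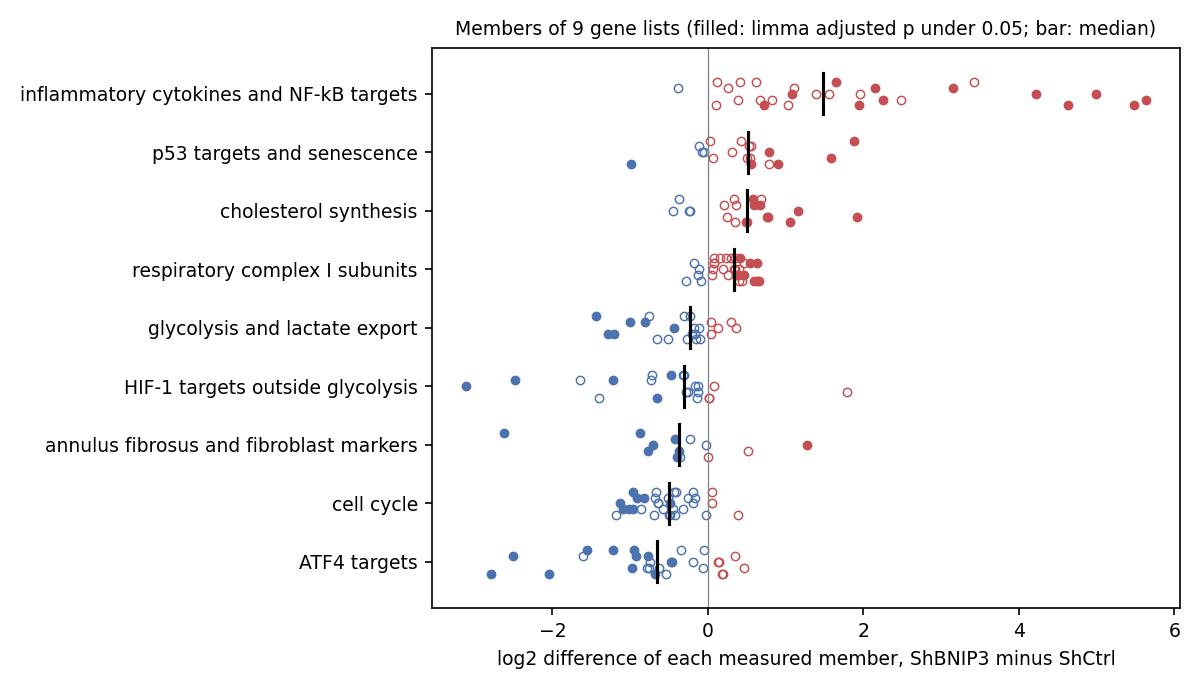
Log2 difference, ShBNIP3 minus ShCtrl (horizontal axis), of each measured member of the 9 gene lists that passed camera at its preset correlation (vertical axis), with a bar at each list's median. Filled points passed a limma adjusted p of 0.05, and the medians run from -0.66 for ATF4 targets to 1.48 for inflammatory genes.

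Cell cycle genes fell in part. Of 32 measured, 8 fell and 0 rose (10 and 0 adjusted over the list alone, 14 and 0 at an unadjusted p under 0.05 in limma), and the list shifted down in camera (adjusted p = 2.29e-05, and adjusted p = 0.717 with an estimated correlation). The mitotic genes Ube2c and Aurkb fell 2.12-fold and 2.03-fold. Members lay a median of 0.01 and -0.39 from the rest of their groups on ShCtrl array 4 and ShBNIP3 array 10, and without these arrays 5 fell, with a list median of -0.52 in place of -0.51 (camera adjusted p = 0.0011, and adjusted p = 0.758 with an estimated correlation). Mki67 and Cenpf did not pass there (log2 -0.94 and -0.81 in place of -1.13 and -0.97, limma adjusted p = 0.0612 and 0.0792). The p53 and senescence list had 5 of 18 up and 1 down, also adjusted over the list alone, with the kinase Plk2 (3.69-fold) and the exonuclease Aen (1.87-fold) among the rises. The apoptosis gene Pmaip1 (NOXA) was the member that fell, 1.99-fold (limma adjusted p = 0.039, over 0.05 in 8 of 10 fits with 1 array left out, at most 0.0935). Its camera adjusted p was 0.0185 (adjusted p = 0.717 with an estimated correlation), 0.0698 without ShCtrl array 4, 0.0596 without ShBNIP3 array 9, 0.0601 among the brighter 50% of probesets and 0.0719 without members shared with other lists. The median log2 difference was 0.51, and 0.36, 0.41, 0.53 and 0.48 in these cases. Its members lay a median of -0.61 and -0.91 from the rest of their groups on arrays 4 and 10, and without these arrays 10 rose and 1 fell. Regulators of apoptosis had 4 of 23 up and 1 down (5 and 1 adjusted over the list alone; camera adjusted p = 0.670), with Casp6 2.27-fold higher and Bok 1.71-fold lower. In the YAP and Hippo pathway 1 of 15 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.781), and the co-activator Wwtr1 (TAZ) was the member that rose, 1.59-fold. The YAP members lay a median of 0.96 and 0.99 above the rest of their groups on arrays 4 and 10.

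Cartilage-type matrix genes had 3 of 25 up and 5 down (3 and 6 adjusted over the list alone; camera adjusted p = 0.289). The collagen-binding proteoglycan Fmod fell 5.18-fold (log2 -2.37, SE 0.37, limma adjusted p = 0.00086), Cilp, at background in ShBNIP3, at least 1.12-fold, and the chondroitin sulfotransferase Chst11 rose 1.88-fold. Col2a1, the cartilage collagen, fell 1.59-fold (log2 -0.67, SE 0.16, limma adjusted p = 0.013). Acan, the main disc proteoglycan, differed by -0.90 (SE 0.42, limma adjusted p = 0.19). It passed without ShBNIP3 array 10 (log2 -1.25, limma adjusted p = 0.028), without arrays 4 and 10 (log2 -0.97, limma adjusted p = 0.020) and with these arrays as a block (log2 -0.90, limma adjusted p = 0.012). Markers of nucleus pulposus cells had 1 of 17 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.594). The carbonic anhydrase Car3 fell 2.45-fold, the galectin Lgals3 2.13-fold and Basp1 1.39-fold, and N-cadherin, Cdh2, at background in ShCtrl, rose at least 1.57-fold.

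Among markers of other cells, those of the annulus fibrosus and fibroblasts fell in part, 7 of 13 down and 1 up, also adjusted over the list alone. The list shifted down in camera (adjusted p = 0.0017, and adjusted p = 0.717 with an estimated correlation). The Wnt modulator Sfrp2 fell 6.14-fold (log2 -2.62, or -3.24 without ShCtrl array 4 and ShBNIP3 array 10), Fbln1 1.83-fold and the surface glycoprotein Thy1 1.71-fold. Postn, a matrix protein of fibroblasts, rose 2.43-fold (limma adjusted p = 0.033, over 0.05 in 7 of 10 fits with 1 array left out, at most 0.0820). Members lay a median of 0.06 and 0.15 from the rest of their groups on these arrays. Above background on at least 1 array were 12 of these 13 markers, and 9 of 12 smooth muscle and pericyte markers. Fbln1 and Thy1 averaged 12.1 and 13.8 even in ShBNIP3. Whether fewer other cells or lower levels in the same cells gave the fall was not tested. Smooth muscle and pericyte markers had 1 of 12 up and 3 down (2 and 3 adjusted over the list alone; camera adjusted p = 0.154). The proteoglycan Cspg4 fell 5.88-fold, desmin, Des, 5.79-fold and the receptor Pdgfrb 1.87-fold, and Mcam, at background in ShCtrl, rose at least 1.89-fold. Their members lay a median of 0.89 above the other ShCtrl arrays on ShCtrl array 4. Without arrays 4 and 10, 4 of these markers rose and 3 fell, with a median log2 difference of -0.16 in place of -0.37. Schwann and neural markers had 2 of 10 down and 0 up, also adjusted over the list alone (3 and 0 at an unadjusted p under 0.05 in limma; camera adjusted p = 0.225), namely S100b, which chondrocytes also express, 4.70-fold, and Ncam1, 2.09-fold. Bone and hypertrophic cartilage markers had 2 of 10 up and 1 down, also adjusted over the list alone (camera adjusted p = 0.616), with osteopontin, Spp1, 1.65-fold higher and the parathyroid hormone receptor Pth1r 1.53-fold lower (limma adjusted p = 0.030, over 0.05 in 6 of 10 fits with 1 array left out, at most 0.0776).

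Skeletal muscle markers had 1 of 12 down and 0 up, also adjusted over the list alone (1 and 1 at an unadjusted p under 0.05 in limma; camera adjusted p = 0.962), and this member, the calcium pump Atp2a1, fell at least 1.14-fold to background. Of 9 adipocyte markers 1 rose and 0 fell, also adjusted over the list alone (2 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.603), and this gene, Fabp4, was at background in both groups. None of 13 endothelial and 7 erythroid markers passed in limma, also adjusted over each list alone (2 and 1 of them were higher at an unadjusted p under 0.05; camera adjusted p = 0.603 for each). The largest differences were 0.40 for Plvap and 0.28 for Slc4a1 on the log2 scale, both at background in both groups.

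With the preset correlation 9 of 37 lists passed, 4 up and 5 down. With a correlation estimated from the data 0 passed in camera, 1 list (annulus fibrosus and fibroblasts) had an unadjusted p under 0.05, and fry called 8. In fry the lists for glycolysis, HIF-1 targets, cell cycle and p53 had adjusted p of 0.164, 0.211, 0.116 and 0.0823, and those for mitochondrial dynamics, NRF2 and Schwann markers 0.0042, 0.0329 and 0.0042. As many as 9 lists also passed the preset test in 18 of 100 splits of the arrays into 5 and 5, the real split included.

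**Figure D4:**
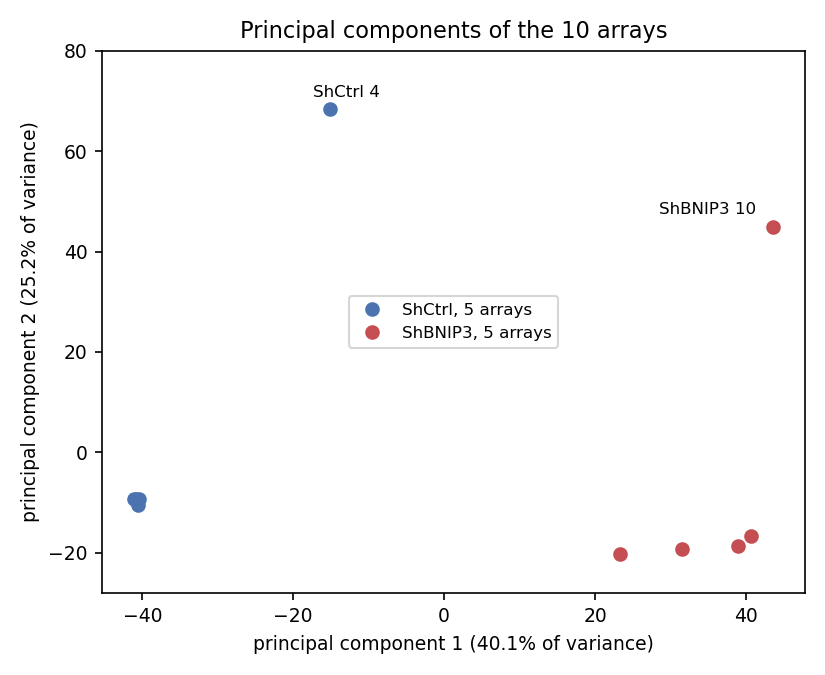
Principal components 1 and 2 of the 10 arrays (both axes in units of the component scores), 1 point per array, blue for ShCtrl and red for ShBNIP3. Component 1 (40.1% of the variance) separates the groups, and component 2 (25.2%) separates ShCtrl array 4 and ShBNIP3 array 10 from the other 8.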

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

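The tests of causes in this part were chosen after the results were seen, except that for cells of another type on arrays 4 and 10, although leaving out each array in turn and fry had been set in advance. Of 314 groups of 5 values examined, 50 (15.9%) held an array far from the other 4, where chance gives about 5%, or 1 in 20. ShCtrl array 4 was the distant one in 33, ShBNIP3 array 10 in 13 and another array in 4.

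On ShCtrl array 4 the inflammatory and matrix genes Ccl2 (15.92), Orm1 (7.55), Mmp13 (16.80), Mmp10 (7.81), Cilp (8.07), Chst11 (11.58) and Postn (9.20) were high on the log2 scale. So were Slc43a2 (8.74), Lims2 (12.83), Bnip3l (15.67), Hmox1 (16.38), Ier3 (13.09), and the oxygen- and glucose-related genes Mxi1 (11.65), Hk1 (13.86), Eno2 (13.41), Stc2 (12.75), Hif1a (15.08) and Slc2a1 (16.91). Low on this array were Anpep (12.95), Adcy8 (9.01), Sumf2 (9.39), Wdr45 (10.93), Srebf1 (8.98), Hadh (9.60), Aars1 (13.29), Sesn2 (12.67), Gstm1 (9.10), Prdx3 (11.08), Cdkn2b (9.66), Pmaip1 (8.73) and S100b (8.25). On ShBNIP3 array 10, Pla2g2a (14.67), Lims2 (8.85), Hk1 (12.70), Pdia6 (14.58), Sel1l (13.94), Mmp9 (10.21) and Tgfbi (16.75) were high, and Anpep (9.50), Sqle (10.54), Sesn2 (11.71), Gstm1 (8.40) and Cdkn2b (10.47) were low. On ShBNIP3 array 6, Mki67 (10.75) and Cenpf (8.10) were high and Mmp13 (17.89) was low. The mean correlation with the own group was low on arrays 4 (0.983) and 10 (0.986), the median of the exon controls on array 4 (10.7) and the background level on ShCtrl array 5 (6.50).

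ShCtrl array 4 and ShBNIP3 array 10 departed from their groups in a shared way, with a correlation of their deviations of 0.527 against at most 0.206 for 24 other pairs. A swap of their labels is excluded by Bnip3, which was -3.29 on array 10 against array 4. Cells of another type in both cultures stay open. Over 9 marker lists the highest of the lower of the arrays' median deviations was 0.0632. In 7 of the lists most markers were at background on all arrays, where a deviation cannot be read. No sign of endothelial or erythroid cells was seen, with 0 of 13 and 0 of 7 markers above background on any array. Lower quality stays open, because the separation of exon from intron controls (AUC 0.896 and 0.900) lay inside the range of the other 8 arrays, while the exon medians (10.7 and 10.96) lay under their lowest of 11.1. No biological explanation was tested, since no label sets these samples apart.

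The rise of the inflammatory list was weighed against other sources. An interferon response is argued against by the 15 interferon genes above background (median 0.0851, upper 95% bound 0.292). More leukocytes in the ShBNIP3 cultures stay open, because 14 of 17 markers (median of all 0.0782) were at background on all arrays, and the other 3 had a median of 1.12. The rise was present without arrays 4 and 10, where the median was 1.90. This was no separate test. The members' deviations, 2.76 on ShCtrl array 4 and 0.96 on ShBNIP3 array 10, already implied a larger difference without these arrays. Pairing of the hairpin with other transcripts stays open, for these rises and for the falls described above. It was not tested, because the hairpin sequence was not used here, and loss of Bnip3 stays open beside it. Of the 100 probesets with the smallest limma p, 86 fell and 14 rose, against 1825 falls and 1765 rises among all that passed.

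The camera result of the glycolysis list rested on ShCtrl array 4. Without this array the median was -0.13 in place of -0.23 and the adjusted p 0.0821 in place of 0.0017. High values on this array alone would leave no fall of the list without it. The remaining median of -0.13 did not pass, so whether this array alone gave the fall of the list stays open. The camera adjusted p over all alternatives with the preset correlation reached 0.0821, and fry gave an adjusted p of 0.164. A fall of single members such as Pfkp, which passed without any 1 of the arrays, stays open as an effect of the knockdown.

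For the counts of probesets a chance division of these 10 arrays can be excluded. A chance difference between cultures or animals cannot, since no label says whether the arrays of a group came from separate ones. Of 100 splits of the arrays into 5 and 5, 1, the real one, gave as many as 3590 probesets, and the highest other gave 292. For changes of at least 2-fold, 1 split, again the real one, gave as many as 969, and the highest other gave 189. Chance cannot be excluded for the number of lists with the preset correlation, since 18 of 100 splits gave at least 9 lists, and the highest other gave 13. The split with 292 probesets exchanged ShCtrl array 4 and ShBNIP3 array 6, which put arrays 4 and 10 on the same side, and the next gave 0.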

How the results depend on the processing

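Leaving out arrays 4 and 10 together, and treating them as a block, were chosen after seeing the data. The number of probesets changed stayed within 1.5 times of 3590 under every alternative except a threshold of 0.01, which gave 1859 because it is stricter. It ranged from 2746 to 3960 with 1 array left out, and from 2989 (complete separation) to 4829 (block) under the others. Changes of at least 2-fold numbered 873 to 1112 with 1 array left out and 847 (treat) to 1168 (without arrays 4 and 10) otherwise, and the log2 difference of Bnip3 was -3.53 to -2.87. The number of lists was 7 to 10 with 1 array left out. With an estimated correlation it was 0 in camera, with all arrays and also 0 without arrays 4 and 10, where 1 and 3 of 37 lists had an unadjusted p under 0.05 and fry called 8 and 18, and the cause was not tested. Of 144 named genes that passed, 119 passed without any 1 of the arrays, and 25 did not in at least 1 case (Acat1, Axl, Birc3, Cdkn2b, Cenpf, Cxcl10, Ddit4, Fads2, Gstm1, Hapln1, Hmox1, Ifih1, Mfn2, Mki67, Ndufb9, Ogdh, Phex, Pmaip1, Postn, Prdx3, Pth1r, Sesn2, Sqle, Stc2 and Tgfbi), with the highest adjusted p of 0.117 for Mfn2. None changed direction. Trib3 had an adjusted p of 0.0565 with a trended and robust variance and Plvap one of 0.0382 with array weights. The MAPK list had 0.0372 with array weights, 0.0316 without arrays 4 and 10 and 0.0336 with the block (with an estimated correlation, adjusted p = 0.687 without these arrays and 0.623 with the block), and glycolysis 0.0621 without these arrays. No paired analysis was possible because the title numbers run 1 to 10 and are shared by no samples. Genes near background, such as 14 of the 17 leukocyte markers, have compressed differences, so small changes in them would not be seen.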

Other observations

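The ribosomal protein genes below and the lists tested in the next paragraph were chosen after results had been seen, but the tests of those lists were set before their values were. Of 70 genes for cytosolic ribosomal proteins, 23 fell and 1 rose in limma, with a median log2 difference of -0.22. All random lists of matched signal had a higher median, but this ranking is no independent support. The set was chosen after results had been seen, and random lists take no account of correlation between genes. Rps10, of the small subunit, fell 6.11-fold (log2 -2.61, SE 0.11, limma adjusted p = 4.36e-08) and Rpl22l1, a paralog of a large subunit gene, 4.29-fold. Without arrays 4 and 10, 24 fell and 1 rose. On the mitochondrial chromosome lie 10 unnamed probesets, with log2 differences of -0.01 to 0.28, of which 0 passed in limma and 0 had an unadjusted p under 0.05. Of the 10, 9 were higher in ShBNIP3. Their mean levels were 14.7 to 19.0, where the array maxima were 19.3 to 19.7. Differences of the brightest may therefore be compressed, and a change cannot be excluded.

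The hypothesis that lower ATF4 output reaches genes outside the fixed list was tested on 12 other ATF4-responsive genes. Of these 4 fell, the synthetases Yars1 (-0.91) and Eprs1 (-0.65) and the amino acid transporters Slc1a5 (-0.83) and Slc38a2 (-0.76). The median of -0.41 lay at percentile 0.55 of matched random lists, which is what the hypothesis predicts. Other causes of a fall in these genes were not tested and would give the same result. Random lists take no account of correlation between genes, so the percentiles in this paragraph do not measure the spread between samples. Fry gave an unadjusted p of 0.034 for this list. The fall did not extend to the mitochondrial tRNA synthetases as a set, of which 13 had a median of 0.19, at percentile 92.7, with 1 (Tars2) up and 0 down in limma. For these 13, whose median was higher in ShBNIP3, fry gave an unadjusted p of 0.0095. A wider inflammatory response was tested on 19 other measured genes of complement, the acute phase and NF-kB signalling. Of these 5 rose, namely Cp (2.62-fold), C1s (2.34-fold), C1r (1.51-fold), and, outside complement and the acute phase, Ripk2 and Il33. The Il33 means, 4.98 in ShCtrl and 5.73 in ShBNIP3, lay under the background level of every array. The median of the 19 genes, 0.59, lay at percentile 100, and fry gave an unadjusted p of 0.030. The share that rose was under the share set in advance, which leaves the hypothesis open.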
